A study of Mus musculus with 4 samples.

How the data were processed

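Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin of isolated nuclei, in pro-B cells sorted from mouse bone marrow. Per the labels' protocols, nuclei were incubated with the transposase for 40 min at 37 °C, and libraries were read in paired-end mode with 50 cycles per read. The 4 libraries fall into 2 genotypes, conditional knockout of Chd4 (cKO, deleted by a Cre recombinase driven from Cd79a) and wild type (WT, littermates), with 2 libraries each. The series calls the samples of a genotype independent. Whether each came from 1 mouse or from a pool is not given in the sources used here, so p-values measure the spread between these samples.

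The authors deposited 1 table of raw counts per peak for all 4 libraries, over a single common peak set. Each library's column was matched to its sample by the name inside the sample's title. The submitters' processing notes name the mm9 build, bcl2fastq, Bowtie2, Picard, SAMtools 1.5, MACS2 2.1.1 and bedtools 2.26.0, with no role or order. Whether reads or fragments were counted, whether ends were shifted for the transposase, how duplicates and mitochondrial reads were treated, and whether peaks were called per library or on pooled libraries is not given in the sources used here. A peak set assembled from both genotypes contains sites because they were open in at least 1 of them, which favours peaks that differ. The table holds 171728 peaks of 306 to 9943 bp (median 439 bp). None of the peaks overlap, and the smallest gap between neighbours is 1 bp. Coordinates are printed as the table gives them, in mm9. Whether starts count from 0 or from 1 is not given in the sources used here, and widths are end minus start.

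No gene annotation of mm9 was used. The gene table at hand describes GRCm38, and coordinates were not moved between builds. Peaks are therefore named by position, and the planned tests of gene lists and of promoter against other peaks were not made. For the same reason peaks at Chd4 itself were not analysed here, so the genotype labels were not checked at the targeted gene. The loci Igl, Tra, Trd and Trg were not analysed here either. The exceptions are 3 antigen receptor loci whose approximate mm9 bounds were fixed, like the tests and the rule for named peaks, before the data were examined: the immunoglobulin heavy chain locus (Igh), the kappa light chain locus (Igk) and the T cell receptor beta locus (Trb). Their peaks are described by the positions of the first and last peak inside those bounds.

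The counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test (glmQLFit and glmQLFTest) with TMM normalization and a design with genotype alone, which leaves 2 residual degrees of freedom. The filter filterByExpr with a minimum count of 10 removed 39 peaks and left 171689. Adjusted p-values follow Benjamini and Hochberg over all tested peaks, and a peak was called at an adjusted p under 0.05. Fold changes are cKO over WT. Their standard errors (SE) are the absolute log2 fold change divided by the square root of the F statistic. Levels are library-size-scaled counts (CPM) after TMM scaling, given as mean ± SD over the 2 libraries of a genotype. The 3 loci were tested as sets with camera of limma 3.58.1 on log2 CPM, with a preset correlation between peaks of 0.01, adjusted over the 3 loci. Runs of neighbouring peaks were compared with 100 random shuffles of the calls within each chromosome.

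The rule for the peaks named in the text takes the 10 largest rises and 10 largest falls among called peaks whose mean log2 CPM lies above the median and whose libraries separate fully by genotype, at most 1 per 100 kb. It adds up to 3 raised and 3 lowered peaks per locus by adjusted p, and the 5 longest runs of at least 4 neighbouring peaks called in 1 direction. Counts were simulated for the same comparison, with 171724 peaks tested and 50 of them changed at each of 4 fold sizes. The fit recovered 20% of the 1.5-fold changes, 60% of the 2-fold changes, and 100% of the 4-fold and 8-fold changes, with 7 false calls among 147. So few changed peaks make the adjusted threshold stricter than in the data, where 64.5% of the peaks were called. The set test called none of 20 unshifted sets of 150 simulated peaks at an unadjusted p under 0.05 and called the shifted set. Simulated peaks were independent of each other, so this does not check the test on the neighbouring peaks of a locus. The estimated correlation between peaks was 0.17 in Igk.

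Library totals ran from 63483353 to 82936611 counts in peaks. Replicate libraries differed by more than sampling noise: the chi-square per degree of freedom of their counts was 4.35 in WT and 5.05 in cKO, so all 4 were kept as separate libraries. The labels do not say that a replicate number marks a shared litter or day, and the design has no replicate block.

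The alternatives were DESeq2 size factors, total counts alone, trended loess offsets, the DESeq2 1.42.0 Wald test, no count filter, a filter at a CPM of 2 in 2 libraries, a fold threshold of 2, no X and Y peaks, each library left out in turn, and the replicate block. Added after the data were seen were the scalings for the loci and the quintiles, the filters and the removal of X and Y for the loci, the refits of the runs, glmTreat against a fold of 1.5, full separation of the libraries, fry, and a comparison of each locus with non-overlapping stretches of as many consecutive peaks, each within 1 chromosome, over the genome.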

Results

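CHD4 is the ATPase of the NuRD complex, which joins nucleosome remodelling with histone deacetylation. The series title places it in transcriptional repression and in the progression of B cell development. Accessibility was measured in pro-B cells, an early B lineage stage in which the immunoglobulin heavy chain genes are assembled, sorted as lineage-negative, CD19- and c-Kit-positive cells without IgM, IgD or CD25. The mice were 4 to 6 weeks old. The single comparison of the design is cKO against WT, with 2 libraries per genotype. WT replicates 1 and 2 held 74224668 and 63483353 counts in peaks, and cKO replicates 1 and 2 held 82936611 and 81128355. Across peaks, which are not independent replicates, the Spearman correlation of counts was 0.976 between the WT libraries and 0.978 between the cKO libraries. Between genotypes it ranged from 0.731 to 0.743. The first principal component of log2 CPM held 90.7% of the variance between the 4 libraries and separated the genotypes.

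Loss of CHD4 was accompanied by changed accessibility at most of the peaks. Of 171689 tested peaks, 57704 (33.6%) were higher and 53037 (30.9%) were lower in cKO, and 60948 (35.5%) were not called by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Among called peaks, the rises were larger than the falls. The median log2 fold change was 1.35 among raised peaks and -0.86 among lowered peaks. The level of a peak affects how small a change is called, and lowered peaks were the stronger ones in WT. At least 4-fold rises were seen at 15899 peaks and at least 4-fold falls at 5467. At least 16-fold rises numbered 1279, against 418 falls of that size. The median level over raised peaks was 0.935 CPM in WT and 2.89 CPM in cKO, and over lowered peaks 3.66 and 1.77 CPM, each median taken separately. Raised peaks took 15.5% ± 0.0495 (SD, n = 2) of all counts in WT and 33.2% ± 0.523 in cKO. Lowered peaks took 56.7% ± 0.0424 in WT and 38.5% ± 0.545 in cKO, so each shift was larger than the spread between replicates. The shares describe peaks chosen for their change. Both cKO libraries lay above both WT libraries at 57606 of the raised peaks, and below at 52942 of the lowered ones. Chance gives such a separation in 1 direction at 16.7% of unselected peaks, a rate that does not apply to peaks already called, since calling nearly fixes their separation. The median over all tested peaks was -0.019, since TMM centres the values, and the split between rises and falls is relative to that centre.

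**Figure D1:**
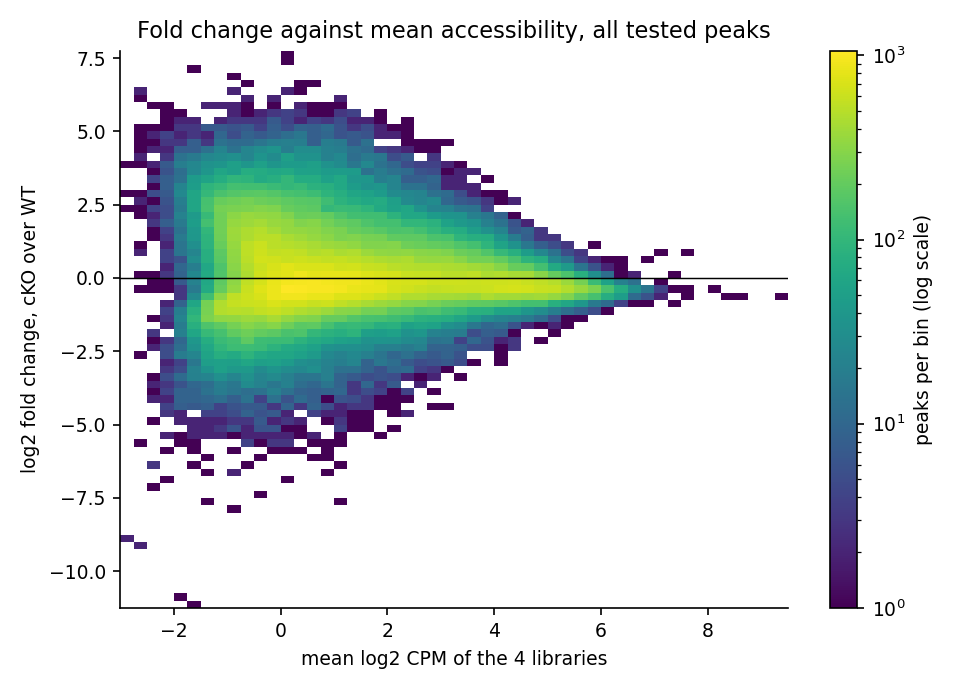
Log2 fold change of cKO over WT (vertical axis) against the mean log2 CPM of the 4 libraries (horizontal axis) for the 171689 tested peaks. The colour gives the number of peaks per bin on a log scale. Changes in both directions extend over most of the range of mean CPM and narrow at the strongest peaks.

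Among called peaks above the median level, to which the rule for named peaks is limited, the 10 largest rises lay on 7 chromosomes. They went from 7 to 42 counts per WT library to 1035 to 1644 counts per cKO library. The largest was a 401 bp peak on chromosome 5, from 7991669 to 7992070. It went from 0.268 ± 0.0268 CPM in WT to 18.9 ± 0.783 in cKO (log2 fold change 6.13, SE 0.172, edgeR, Benjamini-Hochberg adjusted p = 1e-11). A peak on chromosome 8, from 79862208 to 79862613, followed with 0.283 ± 0.0283 against 18.1 ± 0.95 CPM, a 64.0-fold rise. A peak on chromosome 10, from 121850837 to 121851339, rose 60.8-fold. A second peak on chromosome 8, from 127856197 to 127857027, rose 56.0-fold. The other members of the 10 lay on chromosome 5 at 77247820, 18 at 82849427, 4 at 127151956, 1 at 193536216, 17 at 69575332 and 8 at 110739003, with rises of 46.8-fold to 49.4-fold. Benjamini-Hochberg adjusted p-values of all 10 were at most 8.72e-10 in edgeR's test. The 2 WT libraries differed most at the chromosome 4 peak (32 and 7 counts) and at the last chromosome 8 peak (42 and 9 counts). Their log2 fold changes of 5.57 and 5.55 became 6.91 and 6.92 without WT replicate 1, and 4.93 and 4.90 without WT replicate 2.

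Under the same limit on level, the 10 largest falls lay on 9 chromosomes. They went from 710 to 2127 counts per WT library to 9 to 52 counts per cKO library. The largest lay on chromosome 2, from 178663614 to 178664019. It held 26.2 ± 4.51 CPM in WT and 0.131 ± 0.0312 in cKO (log2 fold change -7.62, SE 0.202, edgeR, Benjamini-Hochberg adjusted p = 7.31e-12). Chromosome 6 held the next largest falls, at 135221868 to 135223481 and at 135099260 to 135099663. The first went from 19.3 ± 9.26 to 0.24 ± 0.0386 CPM, and its WT libraries differed, with 922 and 1622 counts. The second went from 14.5 ± 3.08 to 0.276 ± 0.0902 CPM. A peak on chromosome 8, from 96349205 to 96349635, fell from 24.1 ± 2.01 to 0.568 ± 0.0648 CPM. The remaining falls lay on chromosome 1 at 166593323, 10 at 61115923, 11 at 71757912, 17 at 63719306, 5 at 5004703 and 7 at 79397154, and ran from 33.1-fold to 47.9-fold. The log2 fold changes at 61115923 and 71757912, -5.36 and -5.20, were -6.00 and -5.81 without cKO replicate 1. Benjamini-Hochberg adjusted p-values of all 10 were at most 8.91e-10 in edgeR's test.

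**Figure D2:**
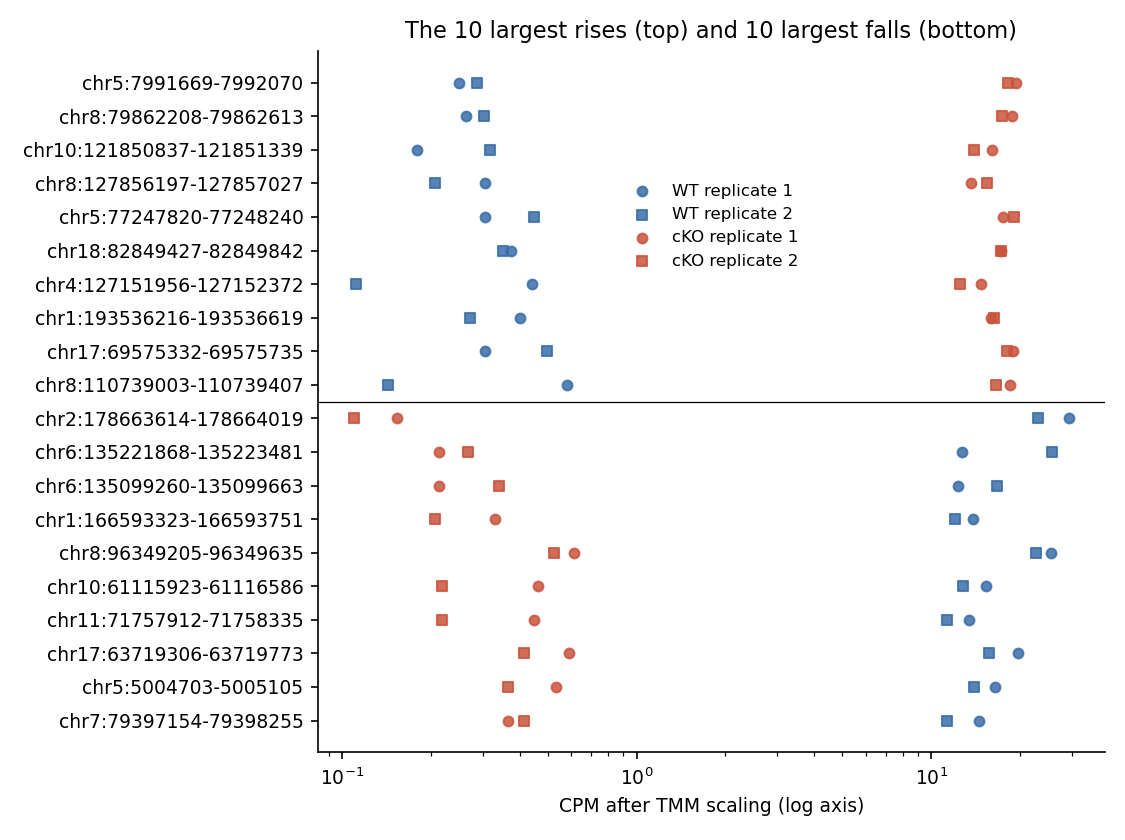
CPM after TMM scaling (horizontal log axis) of the 10 largest rises and the 10 largest falls in each library, with WT in blue, cKO in red, circles for replicate 1 and squares for replicate 2. The 10 raised peaks lie between 0.249 and 0.399 CPM in the WT means and between 13.7 and 18.9 CPM in the cKO means, and the lowered peaks show the opposite order.

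Ranked by WT level, rises were most frequent at weak peaks and falls at strong peaks. In the weakest quintile of peaks by WT mean, 23583 peaks (68.7%) were higher and 1458 (4.25%) lower in cKO, and that quintile's median log2 fold change was 1.51. In the strongest quintile, 5672 (16.5%) were higher and 18544 (54.0%) lower, with a median of -0.27. Part of this order is built in, because a raised peak ranks low by WT alone. Ranked by the mean of all 4 libraries, the weakest quintile held 13092 rises and 8979 falls, close to the 20% of all rises that an even spread gives (22.7%). The strongest quintile of that ranking held 15751 falls (45.9%) and 8442 rises (24.6%). With trended offsets, which remove any average trend with peak strength, that quintile held 12557 falls and 10046 rises. Since these offsets centre the fold changes along peak strength, that balance is no test of an order by strength. Ranked by cKO, which pulls falls to low ranks in the same built-in way, falls were most frequent in the weakest quintile (17166, 50.0%), and the strongest held 13021 falls and 12093 rises.

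**Figure D3:**
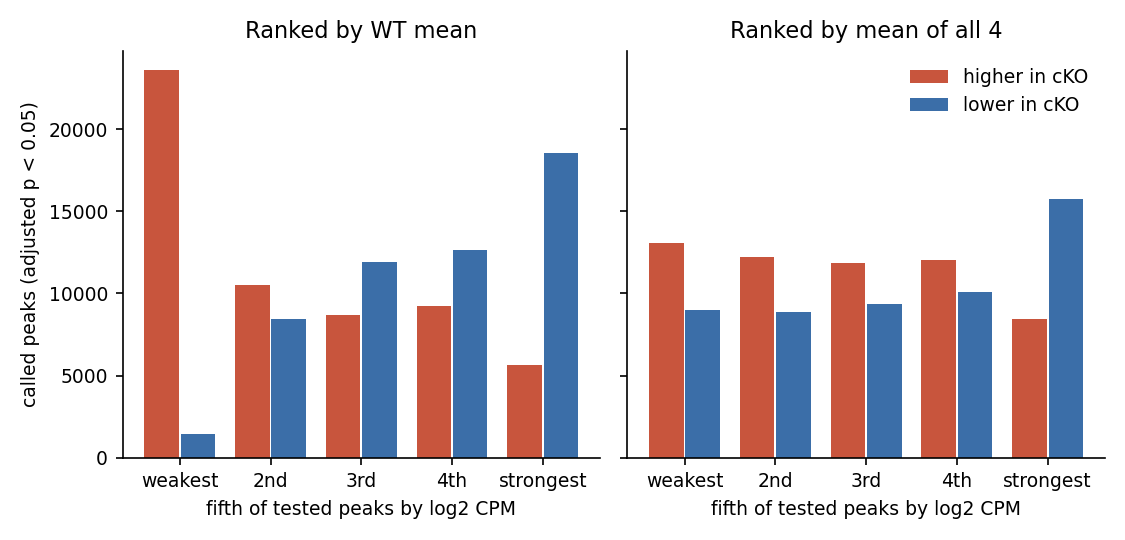
Number of called peaks (vertical axis) higher (red) and lower (blue) in cKO in each quintile of the tested peaks, ranked by WT mean log2 CPM (left) or by the mean of all 4 libraries (right). The weakest WT quintile holds 23583 rises, which drop to 13092 when all 4 libraries set the rank, while falls are most frequent in the strongest quintile under both of these rankings, though not when cKO sets the rank.

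Wide peaks were called lower more often than narrow ones. The median log2 fold change was -0.23 over 2000 bp and 0.0032 up to 500 bp. Width was not separated from level, which also affects how small a change is called. Of 1765 peaks over 2000 bp, which had a median of 14.9 CPM in WT, 847 (48.0%) were lower and 374 (21.2%) higher. Of 106092 peaks of up to 500 bp, with a median of 1.19 CPM, 31211 (29.4%) were lower and 36589 (34.5%) higher. The direction of both classes was the same under each of the 4 scalings tried. All autosomes held changes in both directions. The share of raised peaks per autosome ran from 28.3% on chromosome 3 to 37.6% on chromosome 5. The share of lowered peaks ran from 26.1% on chromosome 11 to 36.0% on chromosome 18.

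The immunoglobulin kappa locus, whose gene segments are usually joined after the heavy chain, was less accessible in cKO. Of 152 tested peaks on chromosome 6 between 67505330 and 70694307, 106 (69.7%) were lower, 16 were higher and 30 were not called. Adjusted over the list alone, the counts were again 106 and 16. The median log2 fold change was -1.62, with an interquartile range from -2.60 to -0.37, and 64 peaks fell at least 4-fold. The fall was not even along the locus. In the 18 peaks from 70522269 to 70694307 the median was -0.054, with 7 lower and 4 higher, and in the 35 peaks from 68003437 to 68439703 it was -0.58, while in the other 5 windows of 0.5 Mb it ran from -3.57 to -1.68. Summed over the locus, the level was 593 ± 52.3 CPM in WT and 309 ± 19.9 CPM in cKO (n = 2 each). The strongest call was a peak from 69990860 to 69991280, which went from 49.0 ± 3.69 to 10.4 ± 0.681 CPM (log2 fold change -2.23, SE 0.0846, edgeR, Benjamini-Hochberg adjusted p = 7.21e-11). Peaks from 67789148 to 67789878 and from 69960637 to 69961068 fell 26.9-fold and 35.2-fold, to 0.632 ± 0.292 and 0.203 ± 0.0129 CPM. Raised peaks lay among the lowered ones. The peak from 69531916 to 69532325 rose from 0.121 ± 0.054 to 3.42 ± 0.516 CPM. The peaks at 68835011 and at 67697437 rose 1.65-fold and 4.93-fold. Without cKO replicate 1, 10 peaks of the locus were called higher and 106 lower. The named Igk peaks had Benjamini-Hochberg adjusted p-values of at most 2.67e-05 in edgeR's test. The set test called the locus lower (camera, Benjamini-Hochberg adjusted p = 1.01e-11). This call was lost with an estimated correlation between peaks (camera, Benjamini-Hochberg adjusted p = 0.509). Among 1117 other non-overlapping stretches of 152 consecutive tested peaks over the genome, 0 had a median as low, and the lowest was -0.88. In the 1 Mb on each side of the locus, 76 of 229 peaks were lower and 64 higher, with a median of -0.074.

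The heavy chain locus, which pro-B cells rearrange, showed changes in both directions that cancelled over the locus. Of 350 tested peaks on chromosome 12 between 114503219 and 117293234, 100 were higher and 82 lower. Adjusted over the list alone, 96 and 79 were called. The median was 0.066 and the locus was not called as a set (camera, Benjamini-Hochberg adjusted p = 0.842, and adjusted p = 0.951 with an estimated correlation). Raised peaks included one from 115786816 to 115787222, which went from 0.0723 ± 0.0346 to 2.57 ± 0.678 CPM, from 7 and 3 counts in the WT libraries. Its log2 fold change of 5.09 was 5.70 without WT replicate 1. The peaks at 115840035 and 116849850 rose 6.03-fold and 9.57-fold. The peaks at 116460803 and 115557122 fell 3.54-fold and 4.03-fold. The 1331 bp peak from 114655062 to 114656393 fell from 20.7 ± 0.163 to 10.1 ± 0.167 CPM (log2 fold change -1.04, SE 0.0943, edgeR, Benjamini-Hochberg adjusted p = 2.36e-07). Counts over V, D and J segments also depend on how many alleles have lost a segment by recombination. The T cell receptor beta locus, which B lineage cells do not use, held 14 raised and 17 lowered peaks among 49 on chromosome 6 between 40840925 and 41494983, with the same counts over the list alone. Its median was 0.19, while camera gave the direction down at a Benjamini-Hochberg adjusted p = 0.842 (adjusted p = 0.951 with an estimated correlation). Peaks at 40980433, 40996566 and 40848892 rose 6.00-fold, 1.60-fold and 2.38-fold. Neighbouring peaks at 40971032, 40965064 and 40968589 fell 7.70-fold, 5.79-fold and 2.82-fold. The named peaks of Igh and Trb had Benjamini-Hochberg adjusted p-values of at most 1.49e-06 and 6.8e-05 in edgeR's test.

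**Figure D4:**
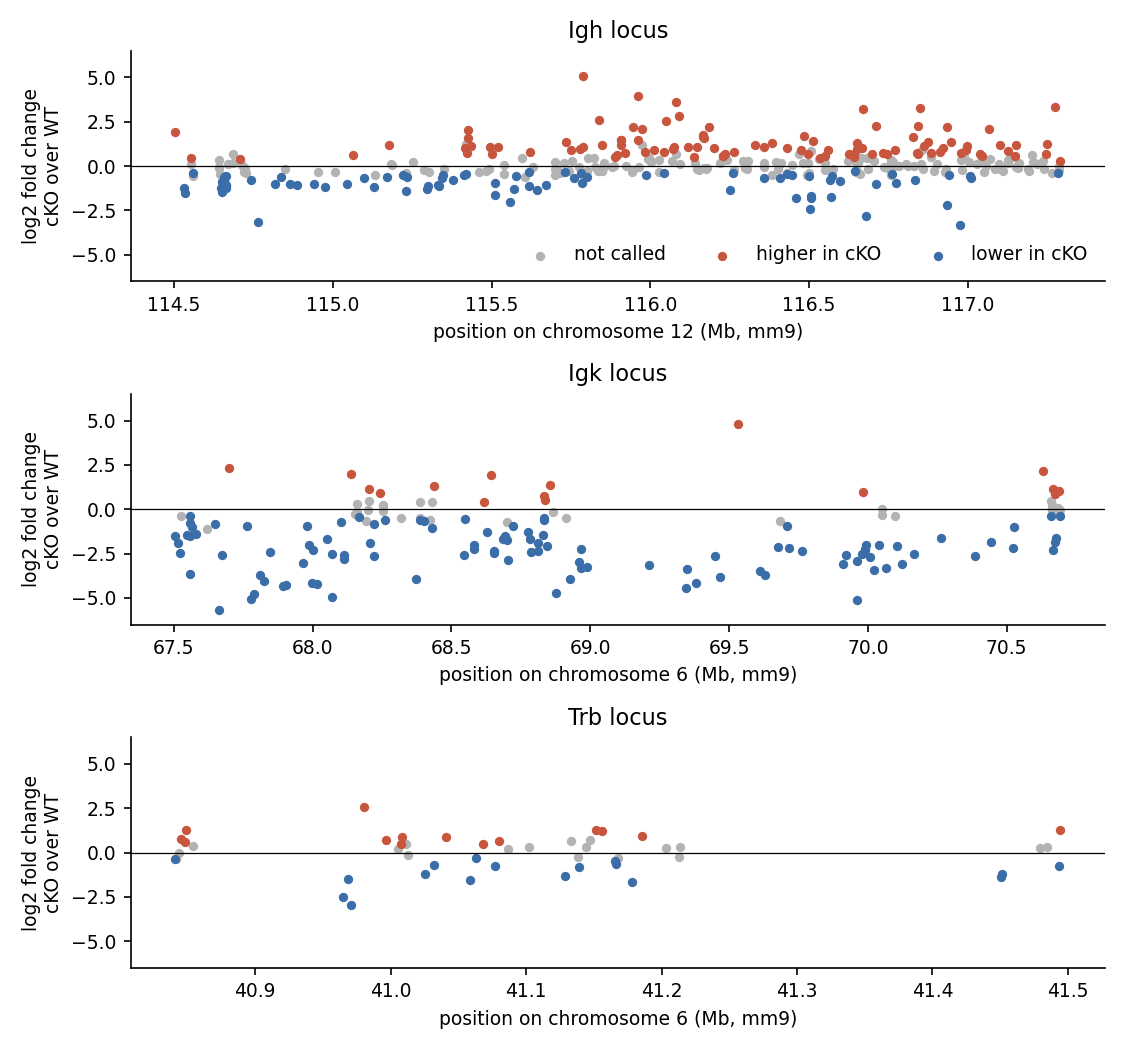
Log2 fold change of cKO over WT (vertical axis) for each tested peak along the Igh, Igk and Trb loci (horizontal axis, position in Mb, mm9), with peaks called higher in red, lower in blue and not called in grey. In Igk 106 of the 152 peaks are lower, while Igh and Trb hold raised and lowered peaks in more even numbers.

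Peaks that changed in the same direction lay next to each other. Runs of at least 4 neighbouring peaks called higher numbered 3309, against a mean of 1480 and a maximum of 1556 in 100 shuffles within chromosomes. Runs called lower numbered 2778, against a mean of 1105 and a maximum of 1182. The shuffles treat all peaks of a chromosome alike, though 65761 adjacent pairs lay under 1 kb apart. Pieces of 1 open region, listed as separate peaks, would form runs as well. The longest runs on autosomes held 28 peaks each. One was a run of raised peaks on chromosome 8, from 124582376 to 124772108, and its summed level went from 26.4 ± 2.12 CPM in WT to 118 ± 1.54 CPM in cKO. The other was a run of lowered peaks on chromosome 9, from 21476259 to 21515099, went from 45.8 ± 4.10 to 16.1 ± 2.45 CPM. A run of 23 raised peaks on chromosome 4, from 153057453 to 153303970, went from 24.2 ± 3.84 to 79.7 ± 5.20 CPM. A run of 25 lowered peaks on chromosome 3, from 25424095 to 25456154, rested mostly on 1 library. It summed to 57.4 and 77.0 CPM in WT replicates 1 and 2, and to 7.61 and 37.8 CPM in cKO replicates 1 and 2. Its median log2 fold change was -1.61 with all libraries, -0.93 without cKO replicate 1 and -3.27 without cKO replicate 2. The longest run of all, 29 peaks called higher on the X chromosome from 47922292 to 47976605, was high in cKO replicate 1 alone, at 165 CPM, against 7.77 CPM in cKO replicate 2 and 4.87 and 4.83 CPM in WT. Without cKO replicate 1 its median fell from 4.10 to 0.18.

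**Figure D5:**
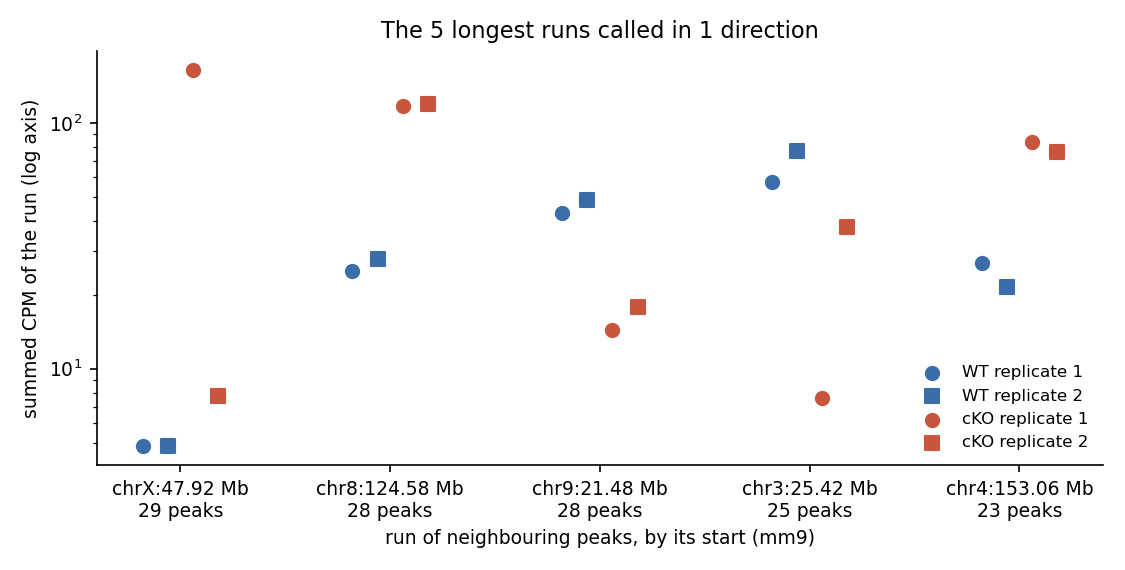
Summed CPM (vertical log axis) of the 5 longest runs of neighbouring peaks called in 1 direction, per library, with WT in blue, cKO in red, circles for replicate 1 and squares for replicate 2. The genotypes separate in the runs on chromosomes 8, 9, 4 and 3, though in the chromosome 3 run the cKO libraries lie far apart, at 7.61 and 37.8 CPM. In the X run only cKO replicate 1 is high.

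The sex chromosomes set 1 library apart. The 77 Y peaks held 84008 and 89071 counts in WT replicates 1 and 2 and 68540 in cKO replicate 2, but 48 in cKO replicate 1. The X share of counts was 2.07% and 2.01% in WT replicates 1 and 2 and 2.05% and 1.92% in cKO replicates 1 and 2. The labels do not give the sex of the mice. Without X and Y peaks, 56847 peaks were higher and 52537 lower, and without cKO replicate 1, 51979 and 45720. Of the Y peaks, 12 were called lower and 0 higher in edgeR's test, a comparison that rests on cKO replicate 1.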

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

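The named loci and peaks kept their direction and their side of the threshold under the alternatives run, except where stated here. Full separation of the libraries, glmTreat, fry, stretches of consecutive peaks, the scalings of the loci and the quintiles, the filters and the removal of X and Y at the loci, and the refits of the runs were chosen after seeing the data. Under 4 scalings, no filter, DESeq2, the replicate block and the removal of X and Y, the counts of raised and lowered peaks stayed within 1.5 times of 57704 and 53037. A fold of at least 2 left 38117 and 21945, a CPM of at least 2 in 2 libraries left 35277 and 34216 because fewer peaks were tested, and glmTreat against 1.5-fold left 39267 and 23064. The share of called peaks that were higher, 52.1%, was 63.5% with the fold threshold, 55.3% with total counts alone, 50.7% with trended offsets, 50.8% with the CPM filter, 53.8% with DESeq2, 63% with glmTreat, and 52.6% to 53.2% with 1 library left out. Trended offsets moved fold changes by a median of -0.14 and turned the call at 224 peaks. With the replicate block, which leaves 1 residual degree of freedom, 59049 and 55006 peaks were called and the share was 51.8%. Same-numbered libraries correlated by 0.083 in their deviations across peaks, and the labels do not say whether same-numbered samples share a litter or day. The count of rises in the weakest WT quintile went from 23583 to 13092 when all 4 libraries set the rank. For Igk the median of -1.62 is the same with an estimated correlation, and the set test's call was lost there, at an adjusted p of 0.509 against 2.63e-14 to 1.99e-09 under the other camera fits. The fry test of limma, which sets the locus against no change and not against other peaks, gave a Benjamini-Hochberg adjusted p of 0.0177. The Igh median, not called, changed sign to -0.045 with trended offsets, -0.010 without cKO replicate 2 and -0.0027 with the CPM filter. Without 1 library the Igk median ran from -1.43 to -1.81 and its lowered peaks from 96 to 106. The share of Y peaks with any count in cKO replicate 1 was 22.1%, against 100% in each other library. All 38 named peaks kept direction and call in their 453 values under the alternatives that tested them. These peaks were chosen for large changes or small adjusted p-values, so this was nearly fixed and is no separate support. Fits without 1 library also leave a genotype with no spread of its own. Of the values of the 5 runs, 10 moved by more than 1 SD and 48 did not, with no change of sign. In the simulation, where 50 peaks changed at each fold size, 20% of the 1.5-fold changes were recovered. In the data 64.5% of the tested peaks were called, which makes the adjusted threshold less strict. The simulated share therefore does not give the sensitivity of the real comparison. Gene lists and promoter classes were not run, for want of an mm9 annotation.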

Other observations

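The tests of neighbouring peaks, of position along Igh, of other cells in either sort, of Igk DNA loss, of genotype and sex at the X cluster, and of peaks private to 1 library were chosen after the result was seen. Fold changes of neighbouring peaks were related over long distances. Across pairs of adjacent tested peaks, which are not independent, the Spearman correlation of log2 fold changes was 0.45 for 65761 pairs under 1 kb apart, 0.26 at 1 to 5 kb, 0.18 at 10 to 50 kb and 0.17 at 50 to 100 kb. After 1 shuffle within chromosomes it lay between -0.028 and 0.038 over the distance classes. Where both peaks of a pair were called, they moved in the same direction in 79.4% of pairs under 1 kb and in 61.2% at 10 to 50 kb. Runs of at least 10 neighbouring peaks numbered 230 for rises and 99 for falls, against at most 7 and 5 in 100 shuffles. These shuffles do not allow for close peaks that are pieces of 1 open region.

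The values along Igh were not even. In the 81 peaks from the first one to 115501020, the end that carries the constant regions, 39 were lower and 12 higher, with a median log2 fold change of -0.47. In the 269 peaks from 115511670 on, 88 were higher and 43 lower, with a median of 0.19 (0.10 without cKO replicate 2). The Spearman correlation of position and fold change over the 350 peaks was 0.30, and 13 of 476 other stretches of as many peaks had one as large in size. These values describe the same peaks whose order prompted the comparison, so they are no independent test of an order along the locus. No explanation was tested.

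That 110741 of the tested peaks differ, in both directions, is the first pattern. Other cells in the cKO sort alone lower a peak 4-fold only where they make up most of the sort, yet 5467 peaks fell that far, and in the WT sort alone they meet the same bound with 15899 peaks that rose as far. A background in cKO that adds an equal density to each peak is argued against as the sole cause of the rises. The median gain of raised peaks was 3.8 times the 5th percentile of density in the cKO libraries. These peaks were chosen for their gain, and a part played by background stays open. That percentile was 0.61 and 0.68 CPM per kb in WT replicates 1 and 2, and 0.81 and 0.82 in cKO replicates 1 and 2. The strongest 1% of peaks held 12.34% and 12.37% of counts in WT, and 10.01% and 9.93% in cKO. Both differences run in the direction of a higher background in cKO. Different stages or cells in both sorts, GC content, the assembly of the peak set and the genotype itself stay open as untested. The 3 splits of 4 libraries are too few for a share under 0.05. The real split, 1 of the 3, called 110741 peaks, and the highest other called 0 in edgeR's test (92 at an unadjusted p under 0.05, with DESeq2 not run on splits). Each other split put both genotypes in each group, where the genotype difference counts as spread. Few calls there follow from this layout.

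The lowered Igk locus is the second pattern. Loss of DNA by recombination as the sole cause would lower all peaks of a stretch, yet 16 peaks of the locus were raised. All of them lay between the outermost lowered peaks, which is fixed, since the first and last tested peaks of the locus were lowered. Of the 16, 14 had a lowered peak as the nearest called neighbour on each side, in a locus where most called peaks were lowered. The raised peaks cannot tell whether DNA loss lowered the other peaks. A change of the whole chromosome region is argued against by the flanks, whose median log2 fold change of -0.074 lay far from the locus. The lowered Igk peaks had a median percentile of 55.7 in WT density, between the bounds set for weak and strong peaks, so a WT signal from few cells at a later stage and a lower opening per cell cannot be told apart. The sort gate excludes CD25-positive and IgM-positive cells.

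The X cluster in cKO replicate 1 is the third pattern. An effect of the genotype is argued against, since cKO replicate 2 reached 1.60 times the WT mean over the run of 29 X peaks while replicate 1 reached 34.0 times. Of 54 peaks in cKO replicate 1 with at least 50 counts and at least 8-fold above each other library, 48 lay on X, in a group of 35 around that run, a group of 12 between 72973815 and 73005189, and 1 at 100676873. Outside the group of 35, which prompted the test, 13 of 19 such peaks (68.4%) lay on X, which holds 2.18% of all peaks, and 12 of the 13 form the second group. With the 48 Y counts of this library, this is consistent with the hypothesis of a female source, though these peaks had been seen beforehand and other causes of a missing Y signal were not tested.

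By the same rule, peaks private to 1 WT library were mostly on chromosome 7, with 8 of 8 in WT replicate 1 and 13 of 18 in WT replicate 2. Of the latter, 9 lay between 36779744 and 36889474, with 3138 counts in WT replicate 2 and 100 to 217 in the other libraries. In cKO replicate 2 there were 3 private peaks, on chromosomes 8 and 14.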
